A study of Homo sapiens with 4 samples.

How the data were processed

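Total RNA of 4 cultures was measured on 1-colour (Cy3) Arraystar human lncRNA arrays, version 3.0 per the labels, 1 array per group. The groups were CAL-27 control, CAL-27 with cisplatin, SCC-9 control and SCC-9 with cisplatin. Cisplatin was given for 24 h at its IC50, and the value of that concentration is not given in the labels. The labels name no replicate cultures, so each line's effect of cisplatin is a difference between 2 arrays.

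Per the file headers, spot brightness was extracted with Agilent Feature Extraction 11.0.1.1, which the submitters' processing notes also name. Per the file headers, the processed signal is an intensity on a linear scale, corrected for background within each array and not normalized between arrays. The deposited value table is on the log2 scale. Per the labels it was quantile normalized, and the sorted values of a line's 2 columns differed by a median of 0.000625 in CAL-27 and 0.000365 in SCC-9 and by at most 0.27, against medians of 1.43 between the control columns and 1.42 between the cisplatin columns of the lines. This is read here as normalization of each line on its own. Its column medians were 4.82 and 4.82 for CAL-27 control and cisplatin and 6.20 and 6.20 for SCC-9 control and cisplatin. Each column correlated across probes with the log2 processed signal of its own array at r = 0.996 or more, with the same direction and no centring of genes. The software behind that table is not given in the sources used here.

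Control spots, 60 negative control probes and spots flagged as outliers were left out, and 81 probes with no unflagged spot on some array were dropped. The log2 processed signals of a probe's spots were averaged, which left 58884 probes. The 4 arrays were then quantile normalized together. On each array, signals below the lowest normalized signal among probes well above background were raised to that signal. This floor lay at 4.60 and 4.96 on the CAL-27 control and cisplatin arrays and at 3.21 and 3.68 on the SCC-9 control and cisplatin arrays. A probe counted as well above background when at least 50% of its unflagged spots carried that flag. Quantile normalization gives the brightest probes values set by their rank, which limits what can be read from small differences of abundant transcripts. No spot was saturated on any array.

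The probes carry no gene names in the files, apart from 20 with a transcript accession. All 20 accessions were matched to a gene symbol through a RefSeq gene table of assembly GRCh38.p14, used for names alone, and 2 of the genes are not reported here. The remaining 58864 probes are unnamed here, and no RNA class, length or coordinate was used for them. Each of the 18 other named genes had 10 spots per array, of which between 6 and 10 were free of outlier flags on each of the 4 arrays. The SE over spots covers the error of measuring 1 labelled sample on 1 array and not the spread between cultures. For the named genes it was computed from log2 processed signals before normalization, while the differences are on the normalized scale. For the GAPDH and PGK1 control probes it was computed on the normalized scale.

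For each line, probes at least 2-fold higher or lower after cisplatin were counted among those well above background on at least 1 of its 2 arrays, with no p-value. The effect of cisplatin over both lines was fitted with limma 3.58.1 in R 4.3.3 with the cell line as a block, since the arrays of a line pair by their label. The fit had n = 2 lines and 1 residual degree of freedom, moderated by a prior with 9.76 degrees of freedom, and used probes well above background on at least 1 of the 4 arrays. The difference between the lines came from the same fit. P-values were adjusted by the Benjamini-Hochberg method and read at 0.05. They and the SEs of the fit rest mainly on a spread pooled over probes by the prior. The probe's own spread between these 4 samples counts for less. In that spread a different response of the lines and the error of the arrays are mixed. The responses of the lines were compared by counts of probes that moved at least 2-fold in the same or in opposite directions, set against the product of the counts divided by the number of probes, and by Pearson and Spearman correlation across probes well above background on all 4 arrays. Probes are not independent replicates, so these correlations carry no p-value.

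The rule for named genes was fixed before the data were examined, as were the groups, the tests of the comparisons, the gene lists and all but 1 of the alternatives. Among the tests of explanations in the closing section, those on end coverage and the counts of probes at least 64-fold apart were chosen later. The rule for named genes takes up to 10 genes each way per line with at least a 2-fold difference and a signal well above background on both arrays. Over both lines it takes up to 10 each way by fold with adjusted p under 0.05 and the same direction, and up to 10 each way by the smaller of the 2 lines' differences. Between the lines it takes up to 10 each way by fold with adjusted p under 0.05. Genes of the Y chromosome and XIST and TSIX are not named. Because so few probes could be named, the other named genes are also described, a choice made after the data were seen. For unnamed probes at most 2 IDs are given each way.

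Of the 36 gene lists, 4 held any named gene and none held the 5 needed for a test, so no list was tested. The cytosolic ribosomal protein list held 3, the hypoxia and glycolysis list 2, the mitochondrial electron transport list 1 and the common reference gene list 3. The relations of response to gene length and to RNA class were not analysed here for the same reason.

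The steps were tested on simulated arrays built from the real probe means, with 200 probes changed in both lines, 50 at each fold. Each probe's variance was drawn from the prior that limma fitted, not from the probe's own residuals. The simulated noise thus follows the model that limma assumes, and recovery on real arrays may be lower. The cisplatin effect over both lines was run on 44986 probes. For it limma recovered 0% of the changes of 2-fold, 8% of 4-fold, 72% of 8-fold and 100% of 16-fold. Of 44786 unchanged probes, 11 were called. These 11 made up 10.9% of all calls, a larger share than the adjusted p threshold is meant to allow. With no response simulated, the correlation of the 2 lines' differences across 29373 probes was -0.01.

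The alternatives were scaling to the 75th percentile, normexp background correction with an offset of 50 followed by quantile normalization, the deposited values, other filters on dim probes, no floor, leaving out saturated probes, thresholds of 1.5-fold and 3-fold, no block for the line, limma's trended and robust variance models, and leaving out each line. Normexp used the median spot and background intensities in place of the mean spot intensity planned for it. Quantile normalization within each line was added after the data were seen. Per the file headers, both arrays of a line were scanned in 1 image and the lines in 2 separate sessions. Slide and line therefore cannot be told apart, and cisplatin was compared within a slide.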

Results

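The expression of long noncoding and other RNAs was measured in CAL-27 and SCC-9 cells, both established lines of human tongue squamous cell carcinoma, with and without 24 h of cisplatin. Cisplatin is a platinum drug that forms adducts on DNA and is a standard treatment of this cancer. Each of the 4 groups was measured on 1 array, so the number of arrays limits the precision of every comparison. Of 58884 probes, 34298 were well above background on the CAL-27 control array and 31705 on the CAL-27 cisplatin array. The SCC-9 arrays were brighter, with 42332 probes well above background in the control and 40023 after cisplatin. The median processed signal was 26.5 and 24.7 on the CAL-27 control and cisplatin arrays and 74.9 and 73.3 on the SCC-9 control and cisplatin arrays. Of 600 spots of negative control probes, 35 and 25 were flagged well above background on the CAL-27 control and cisplatin arrays, and 111 and 94 on the SCC-9 control and cisplatin arrays. The 18 named genes are mostly abundant transcripts of basic cell functions, and 17 of them were well above background on all 4 arrays.

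The first comparison asked which transcripts differed after cisplatin in CAL-27 cells. ODC1, which encodes ornithine decarboxylase, the rate-limiting enzyme of polyamine synthesis, had a normalized log2 signal of 13.30 after cisplatin against 10.92 in the control, a difference of 2.39 ± 0.01 (SE over spots), or 5.24-fold. Its difference exceeded that of 99.3% of probes well above background on both arrays or equalled it. PGK1, which encodes the glycolytic enzyme phosphoglycerate kinase 1, had the only other difference of at least 2-fold among the 17 genes, with -1.04 ± 0.02 on the log2 scale, and lay near that threshold (-0.85 with scaling to the 75th percentile). ARHGDIA, a regulator of small GTPases, differed by 0.89 ± 0.02, PFN1, which encodes the actin-binding protein profilin 1, by 0.86 ± 0.01, and ACTG1, which encodes gamma-actin, by 0.84 ± 0.02. With quantile normalization within each line PGK1 was at -0.94, and PFN1 and ACTG1 were past 2-fold at 1.01 and 1.05. PRMT1, a protein arginine methyltransferase, was the next highest at 0.50 ± 0.01. The named probes of the reference genes fixed as a list did not move alike. That of PGK1, one of these genes, was at -1.04, while ACTB differed by 0.16 ± 0.04 and GAPDH by -0.28 ± 0.02. Control probes for PGK1, described below, differed in CAL-27 by -0.305 and -1.015, so the level of PGK1 itself is left open. The 3 named ribosomal protein genes differed by 0.03 for RPLP1, -0.20 for RPS18 and -0.51 for RPL10, the last a dim probe. The mitochondrial electron transport gene COX4I1 differed by -0.20 ± 0.02.

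Over the whole CAL-27 comparison, 4163 of 35746 probes were at least 2-fold higher after cisplatin and 3852 were at least 2-fold lower, which is 11.7% and 10.8%. The SD of the log2 differences was 0.91. Among 30257 probes well above background on both arrays, 500 were at least 4-fold higher and 557 at least 4-fold lower. The unnamed probe ASHGA5P004760 was highest, at a difference of 6.79, and ASHGA5P038914 followed at 6.42. The unnamed probes ASHGA5P010992 and ASHGA5P051645 were lowest, at -5.47 and -5.40. With 1 array per group these counts have no replicate check, and normexp background correction gave 2087 higher and 2226 lower. Scaling to the 75th percentile shifted the median CAL-27 difference by -0.09 and turned the balance, to 3371 higher and 3863 lower, and so did leaving out the floor, with 4600 and 5028.

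In SCC-9 cells ODC1 again had the largest difference among the named genes, with a normalized log2 signal of 13.13 after cisplatin against 10.39 in the control. This was a difference of 2.74 ± 0.02, or 6.69-fold, at or above that of 99.7% of probes. EIF3D, a subunit of a translation initiation factor, differed by 0.51 ± 0.04 and PGK1 by 0.41 ± 0.02. H3-3A, which encodes a replacement histone H3, differed by -0.42 ± 0.02. ACTG1 differed by 0 ± 0.02, PFN1 by 0.10 ± 0.01 and ARHGDIA by 0.20 ± 0.02. Of the named probes of the 3 reference genes, that of PGK1 had the largest difference, at 0.41. Those of ACTB and GAPDH differed by -0.13 ± 0.01 and 0.07 ± 0.02. RPLP1, RPS18 and RPL10 differed by 0.02, -0.03 and -0.30, and COX4I1 by -0.07 ± 0.02.

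Over the whole SCC-9 comparison, 5371 of 43676 probes were at least 2-fold higher after cisplatin and 3815 at least 2-fold lower, which is 12.3% and 8.73%. The higher probes made up 58.5% of those past the threshold, and 51.9% in CAL-27. Among 38679 probes well above background on both arrays, 561 were at least 4-fold higher and 454 at least 4-fold lower. The unnamed probes ASHGA5P050958 and ASHGA5P049059 were highest, at differences of 7.62 and 5.33, and ASHGA5P046672 and ASHGA5P008113 lowest, at -6.29 and -6.22. Normexp background correction gave 2110 higher and 1592 lower, and scaling to the 75th percentile shifted the median SCC-9 difference by -0.12, after which the balance had turned, with 5067 higher and 5204 lower.

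**Figure D1:**
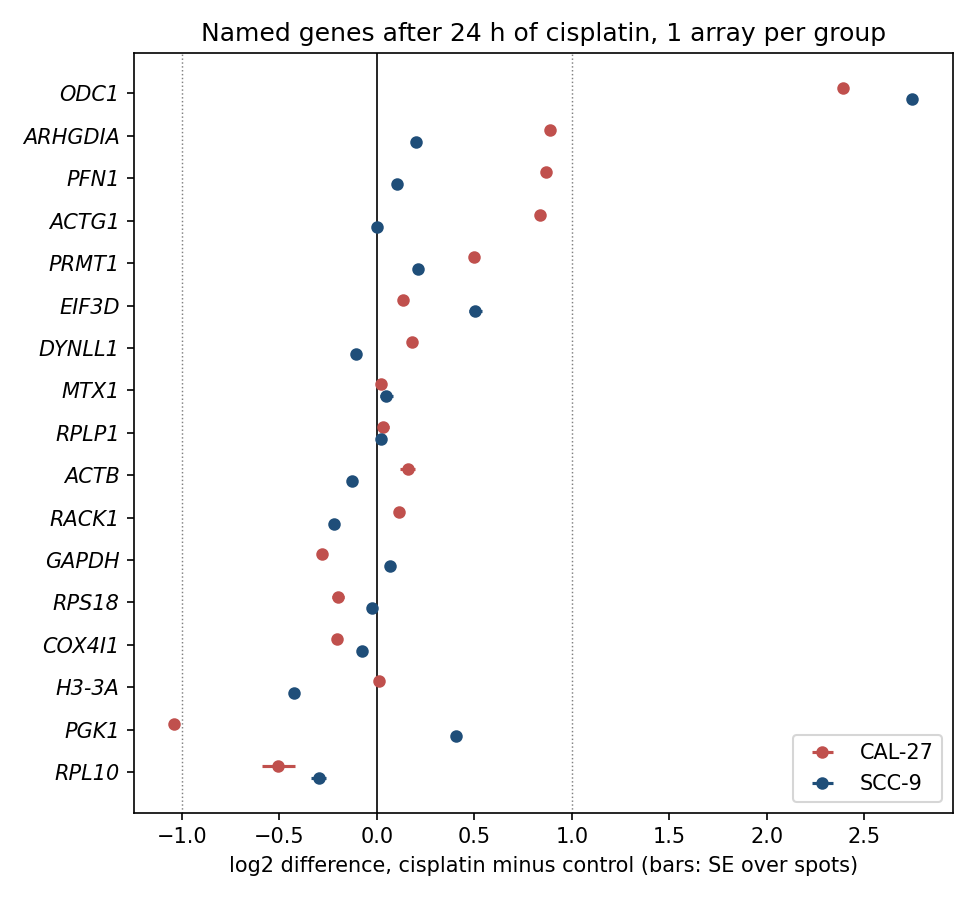
Log2 difference in normalized signal, cisplatin minus control, for the 17 named genes well above background on all 4 arrays, with CAL-27 in red and SCC-9 in blue, 1 array per group, and bars giving the SE over the spots of each probe. Dotted lines mark a 2-fold difference; ODC1 lies at 2.39 in CAL-27 and 2.74 in SCC-9, and PGK1 at -1.04 in CAL-27 and 0.41 in SCC-9.

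The effect of cisplatin over both lines asked which differences were shared by them. ODC1 rose by 2.57 ± 0.43 on the log2 scale (moderated SE, n = 2 lines), or 5.92-fold. It was higher in 2 of 2 lines (limma adjusted p = 0.0326). Among the 18 named genes it was the only one past the threshold, and adjusted over the list alone, the 18 genes, its p was 0.00185. The next largest mean differences were 0.54 ± 0.44 for ARHGDIA (adjusted p = 0.735), 0.48 ± 0.44 for PFN1 (adjusted p = 0.782) and 0.42 ± 0.45 for ACTG1 (adjusted p = 0.825). PGK1, at -0.32 ± 0.48, had differences of opposite sign in the lines (adjusted p = 0.889). Of 44986 probes tested, 87 rose and 152 fell, and 5315 had an unadjusted p under 0.05. All 239 called probes changed by at least 2-fold in both lines. The test imposes this, since disagreement of the lines counts as error in the fit. The floor was higher on the cisplatin array of each line. A probe at the floor on both arrays of a line thus had a built-in rise, of 0.36 in CAL-27 and 0.47 in SCC-9. The median size of the 239 changes was 2.85 on the log2 scale. The smallest was 2.28, a limit set by the test, since the prior keeps the SE of every probe from being small. The unnamed probe ASHGA5P004760 rose by 4.89 ± 0.72 (adjusted p = 0.0232), and ASHGA5P005660 rose by 4.19 ± 0.46 (adjusted p = 0.00967). The unnamed probes ASHGA5P019271 and ASHGA5P009771 fell by 5.12 ± 0.45 (adjusted p = 0.00553) and 4.89 ± 0.48 (adjusted p = 0.0067).

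Of the 239 probes 144 were well above background on all 4 arrays, and the limma count was 0 with normexp background correction (4935 at an unadjusted p under 0.05), with no filter on dim probes (6988) or without the block for the line (668), 81 without the floor (8 higher and 73 lower) and 453 among probes well above background on all arrays (258 higher and 195 lower, a turned balance). For ODC1 the change lay between 2.5 and 2.60 under the alternatives of the fit, and its adjusted p was 0.295 with normexp, 0.202 with no filter, 0.0873 without the floor and 1 without the block.

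The responses of the lines were then set against each other, probe by probe. Across 29373 probes well above background on all 4 arrays, the differences after cisplatin in CAL-27 and in SCC-9 correlated with Pearson r = 0.33 and a Spearman coefficient of 0.27, and 58.2% had the same sign. At least 2-fold higher in both lines were 1160 probes, against 412 for independent lists of those sizes. At least 2-fold lower in both were 531, against 214. In opposite directions were 263, against 600. With no response simulated and the spread of each probe shared by the lines, 206 probes were higher in both against 151 for independent lists, and 420 were opposite against 298, so unequal spreads of probes raise both kinds of count. Of the named genes, ODC1 was at least 2-fold higher in both lines. The unnamed probes with the largest difference held by both lines were ASHGA5P005660, at 4.75 in CAL-27 and 3.63 in SCC-9, and ASHGA5P019271, at -4.65 and -5.59. No gene or probe was tested for a difference between the lines' responses, because that fit leaves no residual degrees of freedom.

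**Figure D2:**
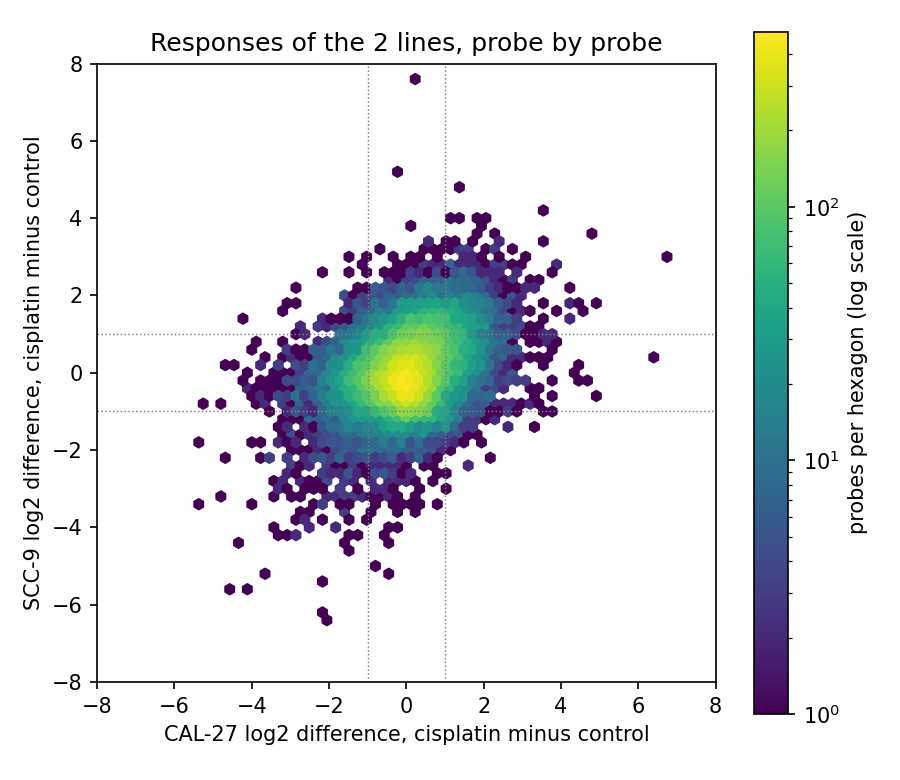
Log2 difference after cisplatin in CAL-27 (x axis) against that in SCC-9 (y axis) for 29370 probes well above background on all 4 arrays, with colour giving the number of probes per hexagon on a log scale and dotted lines marking 2-fold. The cloud leans upward to the right (Pearson r = 0.33), with 1160 probes in the upper right region and 531 in the lower left past both lines.

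More probes differed between the lines than with cisplatin in the same fit. PFN1 was 3.23-fold higher in SCC-9 than in CAL-27, and higher in 2 of 2 treatments. Its log2 difference was 1.69 ± 0.44 (moderated SE, n = 2 arrays per line, limma adjusted p = 0.017). MTX1, which encodes metaxin 1 of the mitochondrial outer membrane, was 3.13-fold lower in SCC-9, at -1.65 ± 0.43 (adjusted p = 0.0163), and lower in 2 of 2 treatments. None of the other named genes passed the threshold in the main fit. H3-3A and DYNLL1, a dynein light chain, were at 1.06 ± 0.43 (adjusted p = 0.0826) and 0.97 ± 0.43 (adjusted p = 0.106), and PGK1 at -1.12 ± 0.48 (adjusted p = 0.097). With scaling to the 75th percentile H3-3A (1.64, limma adjusted p = 0.0112) and DYNLL1 (1.29, limma adjusted p = 0.0279) passed. With no filter on dim probes H3-3A, DYNLL1 and RPL10 passed. ACTB, RPS18 and RPLP1 differed between the lines by 0.14, -0.00 and 0.12 on the log2 scale, and the signs for ACTB and RPLP1 turned with scaling to the 75th percentile and that for RPS18 with normalization within each line. Under the latter ACTB, RPS18 and RPLP1 were at 1.41, 1.33 and 1.57 and passed the threshold, and PFN1 was at 3.51. GRM4, which encodes a glutamate receptor, was well above background on the SCC-9 arrays only and was at least 2.08-fold higher there (adjusted p = 0.0936), counted against the floor of the CAL-27 arrays. The brighter SCC-9 arrays also flagged more negative control probes. These were 10 and 8 of 60 on the control and cisplatin arrays, against 3 and 2 for CAL-27. In all, 5463 probes were called higher and 8356 lower in SCC-9. Part of the lower calls is set by the floor, which lay 1.33 lower on the log2 scale on the SCC-9 arrays and stood in for the signal on at least 1 array for 3142 of them. Tested among probes well above background on all 4 arrays alone, 4528 were higher and 5683 lower, and without the floor 5961 and 5473. The unnamed probes ASHGA5P054207 and ASHGA5P050019 were higher in SCC-9 by 8.11 ± 0.50 and 6.78 ± 0.43, and ASHGA5P035299 and ASHGA5P038633 differed by -8.24 ± 0.46 and -8.12 ± 0.43.

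Line, slide and scan session cannot be told apart in this comparison. The share of calls that were higher in SCC-9 was 39.5%, and 52.1% without the floor, 50.2% with normexp, 44.3% among probes well above background on all arrays and 33.8% with scaling to the 75th percentile, and the call of MTX1 was lost under scaling to the 75th percentile (-0.96, adjusted p = 0.0809). With quantile normalization within each line, which leaves the higher brightness of the SCC-9 arrays in the values, 96.3% of the calls were higher in SCC-9 and MTX1 was at 0.93.

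The arrays also carry pairs of control probes for GAPDH and PGK1 whose names end in 3 and 5, read here as the 3′ and 5′ ends of the transcripts, which is an assumption. For GAPDH the 5′ probe differed after cisplatin by -1.29 ± 0.01 in CAL-27 and by 1.005 ± 0.025 in SCC-9 (SE over spots), and the 3′ probe by -0.25 ± 0.02 and 0.23 ± 0.02. For PGK1 the 5′ probe differed by -1.01 ± 0.03 and 0.93 ± 0.03, and the 3′ probe by -0.30 ± 0.02 and 0.27 ± 0.03. The separate named probe of PGK1, at -1.04 and 0.41, had the sign of these control probes in both lines. Its size was near that of the 5′ probe in CAL-27 and lay between those of the 2 control probes in SCC-9. The named probe thus cannot tell a change in the level of PGK1 from a change in end coverage. How far such shifts entered the 2-fold counts of either line was not tested.

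**Figure D3:**
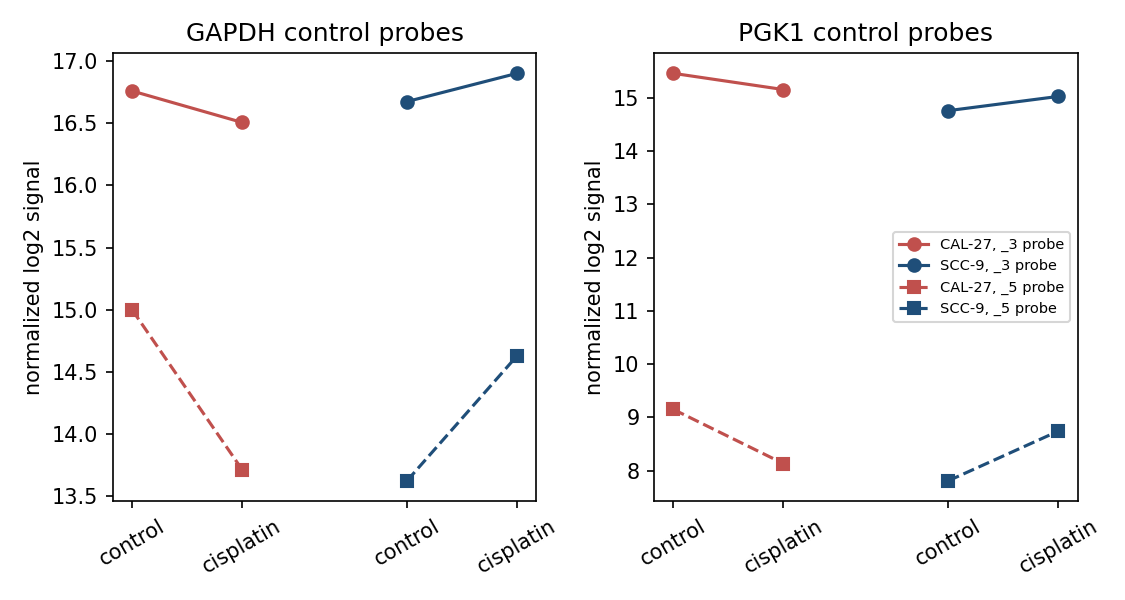
Normalized log2 signal of the GAPDH (left) and PGK1 (right) control probes on the 4 arrays, with circles and solid lines for the 3′ probe and squares and dashed lines for the 5′ probe, CAL-27 in red and SCC-9 in blue; the 2 panels have separate y axes that do not start at 0. From control to cisplatin the 5′ probe of GAPDH went from 14.998 to 13.71 in CAL-27 and from 13.62 to 14.63 in SCC-9.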

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

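The test of end coverage against the correlation of the responses, the test of end coverage against the closeness of the lines, and the counts of probes at least 64-fold apart between the lines in either direction of picking were chosen only after the results were seen. Differences between the lines' responses were not tested, since each line has 1 array per treatment. They are listed where the signs in the 2 lines were opposite and both exceeded 2 times the SE over spots, or where control probe ratios shifted in opposite directions.

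Among the named genes the gap between the log2 differences, CAL-27 minus SCC-9, was widest for PGK1, at -1.45. The gap was 0.28 for ACTB, 0.28 for DYNLL1, 0.34 for RACK1 and -0.35 for GAPDH. Under scaling to the 75th percentile the CAL-27 difference of RACK1 and the SCC-9 difference of GAPDH changed sign, to -0.12 and -0.01. There were 263 probes at least 2-fold higher in one line and at least 2-fold lower in the other, fewer than the 600 of independent lists. The log2 ratio of the 5′ to the 3′ control probe shifted after cisplatin by -1.03 ± 0.02 in CAL-27 and by 0.78 ± 0.03 in SCC-9 for GAPDH, and by -0.71 ± 0.04 and 0.67 ± 0.04 for PGK1 (SE over spots).

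Cisplatin-treated cells of both lines gave fewer probes well above background than their controls, by 2593 in CAL-27 and 2309 in SCC-9. The lowest signal flagged well above background was higher on the cisplatin arrays, at 17.4 against 15.5 in CAL-27 and 21.2 against 17.4 in SCC-9. With 1 signal limit for both arrays of a line, the deficit was 1187 and 680 probes, at most 45.8% of the flagged deficit in either line. A higher detection limit is thus a candidate explanation for more of the deficit than remains, and a loss of transcripts with cisplatin may account for what remains, which was not tested.

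The responses of the lines correlated across probes with r = 0.33. Removing a smooth trend of the difference on mean signal in each line left r = 0.34, and removing the median of each block of 16 by 4 spot positions left r = 0.33, so neither trend accounts for it. A change in end coverage with treatment argues the other way, since the 5′ to 3′ ratio shifted in opposite directions in the 2 lines for 2 of 2 control genes. A shared response to cisplatin is a hypothesis that these tests leave standing. Handling common to both treated cultures, such as time in culture or cell density, stays open and cannot be separated from the drug in this design.

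The CAL-27 and SCC-9 arrays were closer to each other after cisplatin, with Pearson r = 0.7453 between the control arrays and 0.8421 between the cisplatin arrays. The SD of the line difference fell from 1.66 to 1.29. The CAL-27 cisplatin array correlated with the SCC-9 control array at r = 0.7865, also above the pair of controls. For CAL-27 control with SCC-9 cisplatin r was 0.7541. These cross pairs were not used in a test. Noise of dim probes does not by itself explain the closeness, as the SD was 17.2% smaller in the brightest of 5 equal parts of the probes too. A contribution of such noise is not excluded, since the SD was 26.8% smaller in the dimmest part. Of the 500 brightest probes detected in SCC-9 and not in CAL-27 control, 40.6% were well above background in CAL-27 cisplatin, and 30.6% for CAL-27 probes in SCC-9 cisplatin, against 40.8% and 47.6% for the same counts from cisplatin to control, which argues against RNA of either line mixed into the other in bulk. A small mixed share stays open, since of 18 probes at least 64-fold higher in SCC-9 control 14 were higher in CAL-27 after cisplatin (median log2 difference 0.75) and 34 of 59 in the other direction (0.15), but probes picked on the cisplatin arrays were higher in the other line's control in 4 of 7 and 12 of 16 cases (0.61 and 0.69), so picking extreme probes can itself give such counts and they decide nothing. End coverage that became more alike also stays open, because the 5′ to 3′ ratio differed less between the lines after cisplatin for 1 of the 2 genes, GAPDH, and more for PGK1, and so does a response to cisplatin that brings the lines to similar levels, which was not tested.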

How the results depend on the processing

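The alternatives were planned, except quantile normalization within each line, chosen after seeing the data. It and the deposited values moved no count of cisplatin responses by over 1.5 times. They moved the line difference, as both leave the brightness of each line's arrays in the values: 23480 probes were higher and 1527 lower in SCC-9 with the deposited values, and 27462 and 1054 with normalization within each line. The last turned the sign of 9 named genes' line differences, to 1.69 for ACTG1, 2.35 for ARHGDIA, 1.70 for EIF3D, 0.93 for MTX1, 2.12 for ODC1, 2.08 for PRMT1, 1.64 for RACK1, 1.33 for RPS18 and 1.11 for PGK1, of which MTX1 had passed the threshold. Under scaling to the 75th percentile lower probes outnumbered higher ones after cisplatin, with 3371 higher and 3863 lower in CAL-27 and 5067 and 5204 in SCC-9, and without the floor in CAL-27, with 4600 higher and 5028 lower. The higher probes made up 36.4% of those called over both lines and 57.0% among probes well above background on all arrays, with 258 higher and 195 lower. No probe was saturated. Normexp correction gave 2087 higher and 2226 lower in CAL-27, 2110 and 1592 in SCC-9, 513 higher and 269 lower in both lines, 54 opposite, 0 and 0 for the cisplatin effect over both lines (4935 at an unadjusted p under 0.05 with limma), and 3225 higher and 3196 lower in SCC-9 than in CAL-27; its offset shrinks differences of dim probes. By construction the 1.5-fold threshold gave more (8170 and 7446 in CAL-27, 10153 and 9421 in SCC-9, 2989 and 1610 in both, 1588 opposite) and the 3-fold threshold fewer (1493 and 1451, 1826 and 1178, 240 and 156, 13 opposite). For the cisplatin effect over both lines (87 higher, 152 lower), limiting the test to probes well above background on all 4 arrays gave 258 higher, no filter gave 0 and 0 (6988 at an unadjusted p under 0.05), no floor 8 and 73, and the trended variance 132 higher. Without the block for the line, the pairing of arrays by line was ignored and 0 and 0 passed (668 at an unadjusted p under 0.05), since the line difference then counts as error. With the other alternatives between 202 and 314 passed, and 231 of those under scaling to the 75th percentile were among the 239. The overlap was smaller without the floor and among probes well above background on all arrays. Of the 81 probes that passed without the floor, 40 were among the 239. Of the 453 that passed among probes well above background on all arrays, 144 were. Lower in SCC-9 than in CAL-27 were 12711 probes with scaling to the 75th percentile, 26330 with no filter and 5473 with no floor, against 8356; values at the floor carry no order. With no filter 802 probes were lower in both lines. The correlation of the responses was 0.36 with scaling to the 75th percentile and 0.32 with no filter, against 0.33. Except where the construction is named, the cause was not tested. Of the 34 differences of named genes in 1 line, 8 changed sign under some scaling, none above 0.21 in size. Of the cisplatin effects of named genes over both lines, 4 of 204 recomputed values changed side of the threshold, all of ODC1. It lost its call with normexp, no filter, no floor and no block. The 204 include fits without 1 line, which carry no test, and leaving out saturated probes, which removed none. Neither could change side. Of 153 recomputed line differences 21 newly passed the threshold, 14 of them with normalization within each line, and 2 no longer did (both of MTX1). The sign changed for 15, 6 of them under scaling to the 75th percentile and 9 with normalization within each line. Without CAL-27 and without SCC-9 the ODC1 difference was 2.74 and 2.39, with no test. The slide as a block was not run, being identical to the line. The tests of gene lists were not run, and averaging probes of a gene changes nothing with 1 probe each. The SCC-9 arrays measured more probes above background than the CAL-27 arrays, which limits what CAL-27 shows for dim transcripts.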

Other observations

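No hypothesis is tested in this part. The similarity of the responses was seen at every level of signal. In the 5 equal parts of the 29373 probes by mean signal, from dimmest to brightest, the Pearson r between the CAL-27 and SCC-9 differences was 0.25, 0.33, 0.36, 0.40 and 0.29. The SD of the line difference was smaller after cisplatin in each part, by 26.8%, 24.9%, 25.6%, 20.9% and 17.2%. The probes at least 2-fold higher in SCC-9 numbered 6868 between the control arrays and 5050 between the cisplatin arrays, and those at least 2-fold lower 7889 and 6420.

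Of 12 probes for synthetic spike-in RNAs, which are not used in any comparison, 1 was bright on the SCC-9 arrays, with a mean processed signal of 4356 ± 377 in the control and 2276 ± 176 after cisplatin (SD over its 35 spots, less those flagged). On the CAL-27 arrays it was at 49.2 and 90.1, and the highest of the others on any array was at 84.7. The labels do not mention spike-in RNA.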
